A study of Mus musculus with 13 samples.

How the data were processed

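RNA sequencing was done on T cells sorted from C57BL/6J mice, 6 days after a second intravaginal infection with the mouse pathogen Chlamydia muridarum, per the labels' protocols. Mice had been given 2.5 mg medroxyprogesterone, a progestin that makes the genital tract receptive to the bacterium, 1 week before a primary infection with 50000 inclusion-forming units. About 10 weeks after clearance (about 28 days) they were treated again and, 5 days later, reinfected with 500000 units. T helper cells (CD3 and CD4 positive, CD8 and immunoglobulin negative) and cytotoxic-lineage T cells (CD3 and CD8 positive, CD4 and immunoglobulin negative) were sorted from spleen and from genital tract. Each library came from the pooled cells of 2 mice. Spleens were disaggregated mechanically, while genital tracts of the same mice were digested with collagenase and hyaluronidase and then disaggregated. Libraries were made with a stranded mRNA kit. Uninfected animals were not analysed here, so that every comparison is between tissues or between subsets after reinfection.

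The table deposited by the authors held expected counts, that is, estimated read numbers per gene that need not be whole. The submitters' processing notes name STAR 2.7.1, an aligner, and RSEM, which estimates counts per gene, with no RSEM version, and the mouse builds mm39 and mm10, with no role for either. Other alignment and counting settings, including strand, were not given in the sources used here. The values were not scaled to depth, and 29.0% of the values above 0 were not whole. The table had 1 column for each of the 13 libraries and 55416 Ensembl gene identifiers, of which 52083 carried a symbol and 3333 did not, while 67 symbols stood on 2 or more identifiers. Identifiers without a symbol held between 0.208 and 0.458% of the counts of a library. The table gave no coordinates, and the genome annotation at hand was of another build, so no positions are printed. RSEM divides reads that fit several genes between them, and values of near-identical genes (Hspa1a and Hspa1b, Ly6c1 and Ly6c2, Ccl3 and Ccl4, the granzymes and the Klra receptors) are uncertain for that reason.

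Total counts ran from 13507196 to 17820388 per library. Groups were taken from the labels: CD4 cells of spleen (n = 3), CD8 cells of spleen (n = 4), CD4 cells of genital tract (n = 3) and CD8 cells of genital tract (n = 3). No pair of libraries was identical. Over genes with at least 20 counts, the 15 pairs of libraries within groups differed by a chi-square of 16.65 to 85.73 per degree of freedom, more than reads drawn again from 1 library would give. This does not tell separate pools from separate preparations of 1 pool, and libraries were counted as separate because the labels list them as replicates. The labels do not say whether the pools of a group came from separate experiments or days, and p-values therefore measure the spread between these pools. Sequence reads without molecular identifiers are not independent molecules, so floors given for a count of 0 cover counting error only.

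Counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit with robust estimation and glmQLFTest, in R 4.3.3), with trimmed-mean (TMM) scaling, filterByExpr with a minimum count of 10, and 1 fit over all 13 libraries with a mean per group. The filter left 15019 genes, and the common biological coefficient of variation was 0.303. The contrasts were 4 pairwise comparisons (genital tract against spleen in CD4 and in CD8 cells, CD8 against CD4 cells in each tissue) and their interaction, the tissue difference in CD8 cells minus that in CD4 cells. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment, with a threshold of 0.05. CPM values of single genes use the TMM-scaled library total and summed CPM of marker lists the unscaled total, both given as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. A fold against a group whose libraries were all at 0 was computed against 3 counts over the group and is written as a lower bound. Values per library were compared with exact 2-sided permutation tests. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

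Before the data were examined, 21 lists of T cell functions and 13 lists of markers of other cell types were fixed, as were the designs, the processing alternatives except those named as added, and the rule for the genes named. Each list with at least 3 tested members was tested with camera (limma 3.58.1), which compares the list with all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation. Adjustment was over the lists of a comparison. Members past the threshold are counted over all genes tested and, beside that, adjusted over the list alone. Lists share members, up to 15 for the cytokine list. The platelet and megakaryocyte list had under 3 tested members and was not tested. Summed CPM of each cell type list was also computed per library. Named genes were 6 genes of the sort and 20 effector and homing genes in every comparison, of which Il13 was below the filter. To these came the 8 highest and 8 lowest fold changes among genes past the threshold with a mean log2 CPM of at least 4 in the higher group, no overlap between libraries and a named symbol outside the marker lists. Of each list, up to 4 members with the smallest adjusted p were added, or the 2 most expressed where fewer than 2 passed. For the interaction the 6 highest and 6 lowest were taken. Results whose genes are outside this rule say so. Some genes that the rule names are not reported here.

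The alternatives were relative log expression and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom without and with quality weights, a fit of only the groups compared, thinning of all libraries to the smallest total, a fold change of at least 2, leaving out each library in turn, the replicate number as a block and, for lists, leaving out members shared with other lists. Fits over genes with at least 1 CPM in spleen were added after the data were seen. Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. In CD4 and CD8 cells of the genital tract all 3 same-number correlations were between 0.25 and 0.28, so the numbers paired the libraries of that comparison; this rests on the data and not on the labels. The procedure was tested on simulated counts for 15019 genes, with 100 genes changed by each fold. At a 2-fold change 37, 30, 33, 41 and 12% were recovered for the CD4 tissue, CD8 tissue, genital tract subset, spleen subset and interaction contrasts, and at a 4-fold change 63, 68, 66, 69 and 51%. False calls were 5.66, 8.41, 3.88, 3.51 and 5.97% of the calls. Simulated genes varied independently and no other genes were changed, while the real CD4 and CD8 tissue contrasts called 31 and 33.4% of genes. The recovered and false shares therefore need not hold for the real contrasts. Rearranged T cell receptor and immunoglobulin segments and unnamed genes were left out of the genes named.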

Results

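Transcriptomes of CD4 and CD8 T cells were measured by RNA sequencing in 13 libraries from spleen and genital tract of mice reinfected with Chlamydia muridarum 6 days earlier. There were 3 libraries of CD4 cells from spleen, 4 of CD8 cells from spleen, and 3 of each subset from genital tract. Each library was a pool of 2 mice. The title and design text of the series give the purpose as describing T cell profiles of both tissues after secondary infection. Libraries held 13507196 to 17820388 counts. Totals did not part the tissues (exact permutation p = 0.7 in CD4 cells and 0.914 in CD8 cells). Genes with at least 1 count averaged 19118 ± 125 and 19855 ± 792 in CD4 and CD8 cells of the genital tract (n = 3 and 3). In spleen they averaged 18385 ± 564 and 17103 ± 686 (n = 3 and 4). The first 3 principal components held 51.1, 21.5 and 10.4% of the variance.

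The sorted subsets carried the transcripts of their surface markers. Cd4, the co-receptor of helper T cells, averaged 1159 ± 96.8 CPM in CD4 cells of the genital tract and 931.5 ± 50.1 CPM in CD4 cells of spleen. In CD8 cells it averaged 3.98 ± 1.55 and 5.15 ± 7.06 CPM, where the spread in spleen came from library 1, with 15.7 CPM. Cd8a, a chain of the co-receptor of cytotoxic T cells, averaged 1132 ± 107 and 1068 ± 49.4 CPM in CD8 cells of the genital tract and spleen. In CD4 cells it averaged 0.658 ± 0.739 and 1.33 ± 0.39 CPM. Cd3e, part of the T cell receptor complex, had a log2 fold change between tissues of 0.00 ± 0.0991 in CD4 cells (adjusted p = 0.987) and -0.09 ± 0.0928 in CD8 cells (adjusted p = 0.514). The list of 14 sort genes passed in neither subset. In CD4 cells 2 were higher and 6 lower in genital tract, the same adjusted over the list alone (adjusted p = 0.148). In CD8 cells 2 were higher and 4 lower (adjusted p = 0.303).

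Genital tract libraries of both subsets held more transcripts of marker genes of other cell types of that tissue. Spleen libraries held more transcripts of B cell and red cell markers. Marker levels alone do not tell which cells the transcripts came from. Summed markers of fibroblasts and stroma, which include collagen genes, were 664 ± 420 CPM in CD4 and 1359 ± 353 CPM in CD8 cells of the genital tract. In spleen they were 1.0 ± 0.656 and 0.925 ± 0.75 CPM. Neutrophil markers were 388 ± 344 and 936 ± 715 CPM in the genital tract against 5.1 ± 1.91 and 6.95 ± 5.40 CPM in spleen. Epithelial markers were 52.2 ± 21.7 and 308 ± 148 CPM against 7.8 ± 2.01 and 7.68 ± 1.39 CPM. B cell markers went the other way, with 461 ± 135 and 749 ± 122 CPM in the genital tract and 1474 ± 273 and 2255 ± 529 CPM in spleen. So did erythroid markers, with 161 ± 150 and 127 ± 108 CPM against 1548 ± 972 and 1073 ± 400 CPM. No genital tract library overlapped a spleen library of its subset in these 5 measures. With 3 against 3 or 4 libraries an exact permutation test cannot give a p below 0.1 or 0.0571, and 21 measures were compared.

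In the fitted model all 16 fibroblast markers were higher in genital tract in both subsets. The median log2 fold change was 9.53 in CD4 cells, or 8.14 with genes at 0 counts set to their bound (adjusted p = 2.03e-26). In CD8 cells it was 10.8, or 9.63 with bounds (adjusted p = 3.18e-41). Neutrophil markers were higher in CD4 cells for 11 of 13 genes (12 adjusted over the list alone), with a median of 6.63, or 6.20 with bounds (adjusted p = 0.00151, and adjusted p = 0.366 with an estimated correlation). In CD8 cells 12 of 13 were higher, with a median of 6.91, or 6.73 with bounds (adjusted p = 1.03e-04, and adjusted p = 0.264 with an estimated correlation). Epithelial markers were higher for 9 of 11 genes in CD4 cells, with a median of 7.77, or 5.04 with bounds (adjusted p = 4.02e-06, and adjusted p = 0.103 with an estimated correlation). All 11 were higher in CD8 cells, with a median of 7.71 (adjusted p = 2.27e-14). B cell markers were lower for 14 of 16 genes in CD4 cells (16 adjusted over the list alone), with a median of -3.10 (adjusted p = 7.34e-14, and adjusted p = 0.0669 with an estimated correlation). All 16 were lower in CD8 cells, with a median of -3.82 (adjusted p = 7.66e-20). Erythroid markers were lower for 8 of 9 genes in CD4 cells (adjusted p = 4.39e-04, and adjusted p = 0.249 with an estimated correlation) and for 7 of 9 in CD8 cells (7, and 1 higher, adjusted over the list alone, adjusted p = 3.08e-04, and adjusted p = 0.185 with an estimated correlation).

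**Figure D1:**
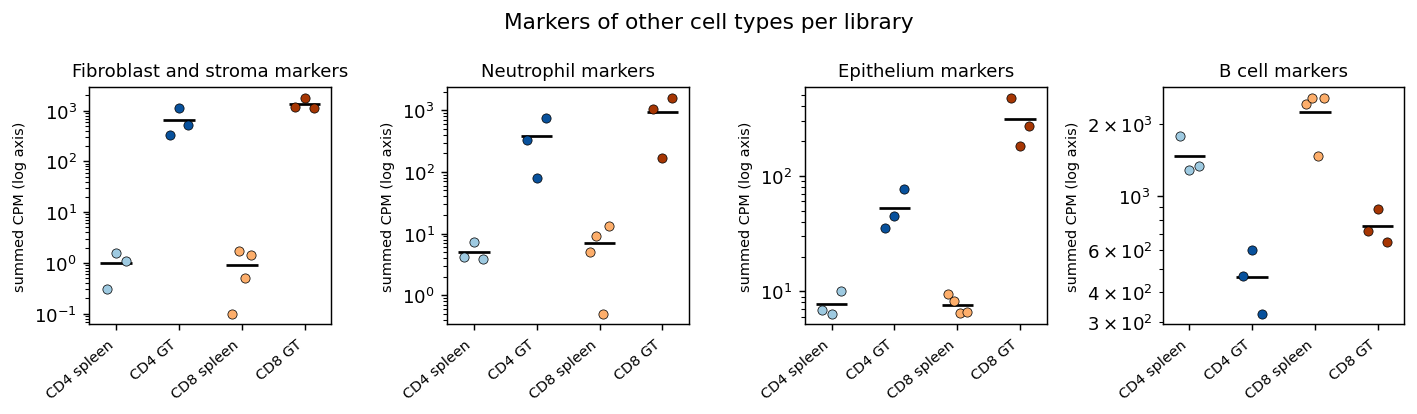
Summed CPM of marker genes of fibroblasts and stroma, neutrophils, epithelium and B cells (log axes, each with its own scale), with 1 point per library and a line at the group mean. Fibroblast markers lie between 333.8 and 1765.5 CPM in the 6 genital tract (GT) libraries and between 0.1 and 1.7 CPM in the 7 spleen libraries, while B cell markers lie between 324.2 and 884.3 CPM in GT and between 1293.8 and 2569.9 CPM in spleen.

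Macrophage markers were higher in genital tract for 10 of 16 genes and lower for 1 in CD4 cells (12 and 1 adjusted over the list alone, adjusted p = 3.04e-04, and adjusted p = 0.249 with an estimated correlation). In CD8 cells 13 of 16 were higher (14 adjusted over the list alone, adjusted p = 4.35e-08, and adjusted p = 0.0902 with an estimated correlation). Natural killer cell markers were higher for 5 of 11 genes in CD4 cells (adjusted p = 0.0277, and adjusted p = 0.354 with an estimated correlation) and 7 of 11 in CD8 cells (adjusted p = 3.32e-05, and adjusted p = 0.105 with an estimated correlation). Endothelial markers did not pass in CD4 cells (3 of 10 higher, 4 adjusted over the list alone, adjusted p = 0.054). They did in CD8 cells (8 of 10 higher, 9 adjusted over the list alone, adjusted p = 0.00239, and adjusted p = 0.266 with an estimated correlation). Smooth muscle markers did not pass in CD4 cells (7 of 9 higher, adjusted p = 0.0837) and did in CD8 cells (9 of 9 higher, adjusted p = 1.12e-04, and adjusted p = 0.23 with an estimated correlation). Lists of mast cells (1 of 3 higher in each subset, 3 adjusted over the list alone, adjusted p = 0.146 and 0.08), dendritic cells (4 of 13 higher in CD4 cells, 3 higher and 2 lower in CD8 cells, adjusted p = 0.296 and 0.799) and plasma cells (1 of 8 higher in each subset and 4 lower in CD8 cells, adjusted p = 0.862 and 0.0991) passed in neither subset. In CD8 cells the dendritic list had a median of 0.84 while its test pointed down. The platelet list had too few tested genes.

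CD4 cells of the genital tract carried many times more effector cytokine transcripts than CD4 cells of spleen. Ifng (ENSMUSG00000055170), the interferon-gamma gene, averaged 1602 ± 471 CPM against 48.7 ± 18.0 CPM (log2 fold change 5.04 ± 0.476, adjusted p = 6.1e-06). Il17a (ENSMUSG00000025929), which encodes a cytokine that draws neutrophils, averaged 55.4 ± 26.3 CPM against 0.714 ± 0.594 CPM (6.30 ± 0.741, adjusted p = 3.98e-05). Ccr7 (ENSMUSG00000037944), the chemokine receptor for lymph node entry, was lower at 106 ± 17 against 1832 ± 159 CPM (-4.11 ± 0.389). The 3 genital tract libraries did not overlap the 3 spleen libraries for any of these genes, which chance gives for 10% of genes.

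Of 18 type 1 helper genes 16 rose and 1 fell, the same adjusted over the list alone (median log2 fold change 2.67, adjusted p = 1.02e-22). Tbx21, the lineage-defining transcription factor T-bet, rose by 3.24 ± 0.185 on the log2 scale, the receptor Cxcr3 by 2.64 and Tnf by 2.93. Eomes (ENSMUSG00000032446), a related transcription factor, was the one that fell, by 2.74 on the log2 scale. Of 15 type 17 helper genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 3.98, adjusted p = 2.55e-11). Il17f rose by 7.68 ± 0.901 and Il21 by 3.83. The type 2 helper list did not pass (3 of 9 higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.0856). Its member Il1rl1, the interleukin-33 receptor, rose by 3.40 ± 0.654, while Gata3, which directs type 2 differentiation, had 0.06 ± 0.156 (adjusted p = 0.806).

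Secreted chemokines and cytokines rose for 22 of 26 genes and fell for 1, the same adjusted over the list alone (median 3.38, adjusted p = 8.61e-19). Csf2, the GM-CSF gene, averaged 51.8 ± 15.8 against 0.559 ± 0.287 CPM (6.50 ± 0.507), and Il2 rose by 3.84. Of 18 chemokine receptors 10 rose and 2 fell (14 and 3 adjusted over the list alone, adjusted p = 4.31e-08). Ccr2 rose by 4.67, and Cxcr6, a receptor of tissue T cells, averaged 1892 ± 244 against 65.2 ± 30.8 CPM (4.86 ± 0.333). Cytotoxicity genes rose for 17 of 19 and fell for 1, the same adjusted over the list alone (median 2.05, adjusted p = 1.28e-14). Gzmb (ENSMUSG00000015437), the protease granzyme B, averaged 420 ± 151 against 11.3 ± 2.0 CPM (5.22 ± 0.332, adjusted p = 1.78e-07). Nkg7, a protein of cytotoxic granules, rose by 2.86 and the chemokine gene Ccl4 by 5.08. Innate-like T cell genes rose for 8 of 18, the same adjusted over the list alone (adjusted p = 0.00475, and adjusted p = 0.294 with an estimated correlation), among them the receptor gene Klrk1 (3.14 ± 0.363). Natural killer cell markers, which share members with the cytotoxicity and innate-like lists, were at 276 ± 29.5 CPM against 82.7 ± 19.7 CPM in spleen.

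Of 23 residency genes 15 rose and none fell (15 and 1 adjusted over the list alone, median 1.97, adjusted p = 7.93e-09). Itga1, an integrin that binds collagen, averaged 84.0 ± 8.77 against 1.34 ± 0.398 CPM (5.97 ± 0.552), and Prdm1, the transcription factor Blimp-1, rose by 2.38. Cd69, the receptor that holds T cells in tissue, had 0.15 ± 0.119 (adjusted p = 0.367), and Itgae, the integrin that binds epithelium, 0.65 ± 0.287 (adjusted p = 0.102). Naive and stem-like genes fell for 18 of 21 and rose for none, the same adjusted over the list alone (median -2.07, adjusted p = 3.32e-31). Igfbp4 had -4.52 ± 0.217, Lef1, a transcription factor of naive cells, -2.40, and Cd27 -2.11. Recirculation genes fell for 8 of 15 and rose for 3, the same adjusted over the list alone (adjusted p = 8.85e-07).

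Regulatory T cell genes rose for 9 of 20 and fell for 1 (10 and 1 adjusted over the list alone, median 0.94, adjusted p = 5.03e-05). Entpd1, an enzyme that breaks down extracellular ATP, rose by 3.35. Foxp3 (ENSMUSG00000039521), the factor that defines these cells, averaged 120 ± 30.7 against 112 ± 16.4 CPM (0.10 ± 0.362, adjusted p = 0.864), and Il10 had 0.11 ± 0.616 (adjusted p = 0.91). Inhibitory receptor genes rose for 7 of 15 and fell for 1 (8 and 2 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). Pdcd1, the PD-1 gene, averaged 176 ± 38.4 against 34.1 ± 8.97 CPM (2.37 ± 0.285), Havcr2 rose by 6.15 and Tox fell by 2.09 on the log2 scale. The follicular helper list did not pass (4 of 10 higher, 3 lower, the same adjusted over the list alone, adjusted p = 0.529).

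Tissue repair and growth factor genes rose for 12 of 20 (13, and 1 lower, adjusted over the list alone, adjusted p = 4.84e-05). They included the protease genes Furin (4.80 ± 0.401) and Mmp9 (4.81 ± 0.522), in libraries where neutrophil markers were at 388 against 5.1 CPM and fibroblast markers at 664 against 1.0 CPM. Plac8 (ENSMUSG00000029322), a small cysteine-rich protein, averaged 269 ± 42.6 against 9.18 ± 2.18 CPM (4.88 ± 0.241). Areg, the growth factor amphiregulin, had 1.07 ± 0.823 (adjusted p = 0.35, but 0.0243 with quality weights and 0.0498 when only these groups were fitted). Glycolysis and hypoxia genes rose for 20 of 23 and fell for 1 (21 and 1 adjusted over the list alone, median 0.98, adjusted p = 2.55e-11). Tpi1, a glycolytic enzyme, rose by 2.49 ± 0.143, while Pdk1, a kinase that restrains the oxidation of pyruvate in mitochondria, fell by 2.46 on the log2 scale. Proliferation genes rose for 22 of 34 (27 adjusted over the list alone, median 1.59, adjusted p = 5.09e-06, and adjusted p = 0.354 with an estimated correlation), with Mcm3, part of the replication helicase, at 1.11. Interferon-stimulated genes rose for 14 of 31 and fell for 1, the same adjusted over the list alone (adjusted p = 6.97e-04, and adjusted p = 0.506 with an estimated correlation), with Isg15 at 1.86. Cholesterol genes (5 of 20 higher, 3 lower, adjusted p = 0.997) and immediate early genes (7 of 26 higher, 2 lower, adjusted p = 0.296) did not pass as lists, with the same counts adjusted over the list alone.

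The heat shock genes Hspa1a (ENSMUSG00000091971) and Hspa1b, a near-identical pair of inducible chaperones, averaged 10690 ± 3530 and 16550 ± 4560 CPM in CD4 cells of the genital tract, which was the tissue digested with enzymes. In spleen they averaged 5.32 ± 2.88 and 9.65 ± 4.31 CPM (log2 fold changes 10.99 ± 0.545 and 10.75 ± 0.517). Of 16 heat shock genes 12 rose and 1 fell, the same adjusted over the list alone (median 1.02, adjusted p = 7.52e-07, and adjusted p = 0.249 with an estimated correlation). Other genes among those with the highest fold changes rose in libraries where fibroblast, epithelial and neutrophil markers also rose. Saa3, an acute-phase protein, was at least 935-fold higher, Plet1 at least 345-fold, Guca2b at least 331-fold and Ccn1 at least 329-fold, all with 0 counts in spleen. Prap1, an epithelial gene, averaged 285 ± 209 against 0.147 ± 0.255 CPM (10.99 ± 1.82). With limma-voom Prap1 did not pass (adjusted p = 0.403), nor did Guca2b (0.447) or Plet1 (0.0711). Among the lowest were Slc16a5 (-5.23 ± 0.425), Gabrr2 (-4.51), Atp1b1 (-4.51), St8sia6 (-4.38), Pdlim4 (-4.24) and Dapl1 (-4.15).

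In all, 4660 of 15019 genes passed in CD4 cells, 2752 higher and 1908 lower in genital tract. With an estimated correlation the calls of the type 1 and type 17 helper, cytotoxicity, residency, recirculation, naive, regulatory, chemokine receptor, cytokine, repair, glycolysis and fibroblast lists held, the weakest being the regulatory list (adjusted p = 0.0486). Over the 12165 genes with at least 1 CPM in spleen, an alternative chosen after the data were seen, 3774 genes passed. Of these 51.6% were higher in genital tract, against 59.1% over all genes. A lower share follows from the filter itself, which removes genes that are low in spleen.

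**Figure D2:**
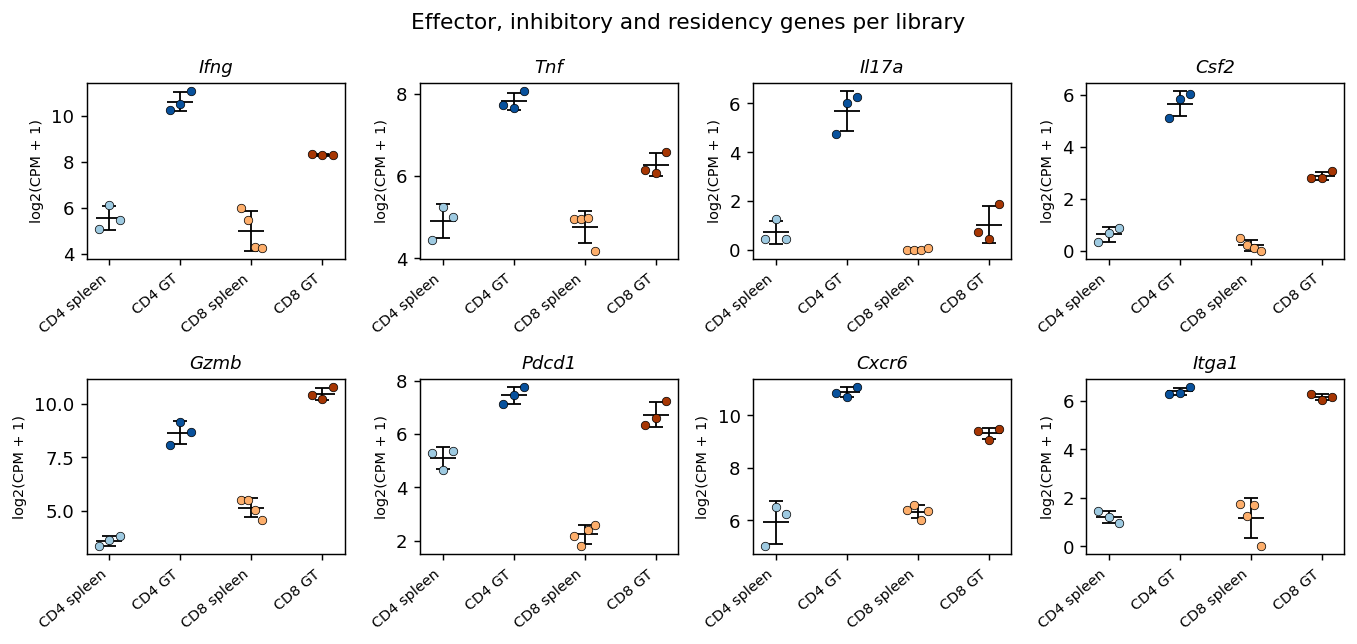
Expression of Ifng, Tnf, Il17a, Csf2, Gzmb, Pdcd1, Cxcr6 and Itga1 as log2(CPM + 1), with 1 point per library and black marks for the mean and bars for the SD on that scale in each of 4 groups. Every genital tract (GT) library lies above the spleen libraries of its subset, with Ifng at a mean of 1602 CPM in CD4 and 316 CPM in CD8 cells of GT against 48.7 and 35.9 CPM in spleen.

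CD8 cells of the genital tract differed from CD8 cells of spleen by more cytotoxic, inhibitory receptor and chemokine transcripts. Gzmb averaged 1428 ± 294 CPM (n = 3) against 36.0 ± 10.2 CPM (n = 4), a log2 fold change of 5.31 ± 0.29 (adjusted p = 1.93e-07). Ifng averaged 316 ± 10.1 against 35.9 ± 21.6 CPM (3.13 ± 0.392, adjusted p = 9.12e-05) and Pdcd1 109 ± 36.7 against 3.83 ± 1.1 CPM (4.85 ± 0.297). Ccr7 was lower at 426 ± 104 against 3397 ± 1740 CPM (adjusted p = 6.43e-05). No genital tract library overlapped a spleen library for these 4 genes.

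Of 19 cytotoxicity genes 16 rose, the same adjusted over the list alone (median 1.31, adjusted p = 2.66e-11), with the granzyme genes Gzma and Gzmk up by 3.38 and 3.32. Type 1 helper genes rose for 15 of 18 (16 adjusted over the list alone, median 1.64, adjusted p = 3.81e-13), including Tnf (1.52 ± 0.225) and Tbx21 (1.99 ± 0.159). Inhibitory receptor genes rose for 10 of 15 and fell for 1, the same adjusted over the list alone (median 1.63, adjusted p = 4.13e-06), including Lag3 (4.44) and Entpd1 (3.31). Secreted chemokines and cytokines rose for 22 of 26 and fell for 1, the same adjusted over the list alone (median 3.18, adjusted p = 1.01e-14). Ccl3, a chemokine of activated cytotoxic cells, rose by 4.50, Csf2 by 5.21, and Il10 from 0.196 ± 0.232 to 2.43 ± 0.232 CPM (3.48 ± 0.7). Interferon-stimulated genes rose for 25 of 31 (27, and 1 lower, adjusted over the list alone, median 1.39, adjusted p = 4e-10, and adjusted p = 0.224 with an estimated correlation). Rsad2, an antiviral enzyme, rose by 3.12 and Isg15 by 2.21.

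Type 17 helper genes rose for 12 of 15 and fell for 2 (13 and 2 adjusted over the list alone, median 3.75, adjusted p = 1.08e-06), at low levels. Il17a averaged 1.26 ± 1.27 CPM against 1 count in all 4 spleen libraries. The type 2 helper list did not pass (5 of 9 higher, 1 lower, the same adjusted over the list alone, adjusted p = 0.068). Regulatory T cell genes rose for 14 of 20 and fell for 2, the same adjusted over the list alone (median 1.09, adjusted p = 5.74e-06), with Il2ra, the interleukin-2 receptor alpha chain, at 3.43. Foxp3 itself averaged 0.853 ± 0.753 against 2.56 ± 1.37 CPM (-1.56 ± 0.539, adjusted p = 0.0396). That call was lost with no filter (adjusted p = 0.127), with limma-voom (0.148), and without CD8 spleen library 1 or 4 (adjusted p = 0.0915 and 0.102) or genital tract library 1 or 2 (0.125 and 0.118).

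Residency genes rose for 15 of 23 and fell for 2, the same adjusted over the list alone (median 1.82, adjusted p = 1.84e-05, and adjusted p = 0.105 with an estimated correlation). Itga1 rose by 5.51 ± 0.478, and Cxcr6 averaged 638 ± 93.1 against 80.0 ± 13.2 CPM. Cd69 fell from 1305 ± 145 to 620 ± 40.6 CPM (-1.08 ± 0.115, adjusted p = 2.61e-05) and Itgae from 138 ± 22.7 to 47.5 ± 13.7 CPM (-1.54 ± 0.263, adjusted p = 0.0008). Naive genes fell for 16 of 21 and rose for 1, the same adjusted over the list alone (median -0.87, adjusted p = 4.57e-11). The transcription factors Lef1 and Foxp1 had -1.56 and -1.13, and the gut-homing receptor Ccr9 -3.94 ± 0.291. Recirculation genes fell for 6 of 15 and rose for 4 (8 and 5 adjusted over the list alone, adjusted p = 0.0239, and adjusted p = 0.12 with an estimated correlation).

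Repair genes rose for 13 of 20, the same adjusted over the list alone (adjusted p = 4.62e-06), with Mmp9 at 5.67 and Plac8 at 258 ± 57.8 against 101 ± 15.8 CPM (1.35 ± 0.186). Neutrophil and fibroblast markers were at 936 and 1359 CPM in these libraries against 6.95 and 0.925 CPM in spleen. Mmp9 was near 0 in spleen, at 0.13, 1.365, 0 and 0.0756 CPM in libraries 1 to 4, so the size of its fold change rests on few counts. Chemokine receptors rose for 10 of 18 and fell for 4, the same adjusted over the list alone (adjusted p = 0.00234, and adjusted p = 0.0948 with an estimated correlation). Innate-like genes rose for 13 of 18 (14 adjusted over the list alone, median 2.32, adjusted p = 3.26e-06, and adjusted p = 0.0902 with an estimated correlation), with Klrk1 at 2.84. Natural killer cell markers, which share members with that list and with the cytotoxicity list, were at 714.5 ± 226.4 CPM against 145 ± 31.9 CPM in spleen. Follicular helper genes rose for 4 of 10 (5, and 1 lower, adjusted over the list alone, adjusted p = 0.0367, and adjusted p = 0.126 with an estimated correlation). Glycolysis genes rose for 11 of 23 and fell for 1 (12 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.0338, and adjusted p = 0.296 with an estimated correlation), with Tpi1 at 1.06. Proliferation genes rose for 7 of 34 (3 adjusted over the list alone, adjusted p = 0.00974, and adjusted p = 0.538 with an estimated correlation). Mki67, a gene of dividing cells, averaged 35.5 ± 3.5 against 7.63 ± 7.82 CPM. Immediate early genes (5 of 26 higher, 7 lower, 5 and 8 adjusted over the list alone, adjusted p = 0.303) and cholesterol genes (5 of 20 higher, 5 lower, 7 and 5 adjusted over the list alone, adjusted p = 0.713) did not pass as lists. The cholesterol list had a median of 0.30 while its test pointed down.

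Heat shock genes rose for 8 of 16 and fell for 2 in CD8 cells, the same adjusted over the list alone (median 0.60, adjusted p = 4.69e-06, and adjusted p = 0.224 with an estimated correlation). Hspa1a averaged 9132 ± 3330 against 5.23 ± 1.41 CPM (10.78 ± 0.473), again in the tissue digested with enzymes, and its co-chaperone gene Dnajb1 rose by 2.38. Other genes among those with the highest fold changes rose beside the fibroblast and epithelial markers. C1s1, a complement protease gene, was at least 1280-fold higher, Sprr2f, an epithelial gene, at least 1020-fold, Gas6 at least 688-fold and Adamts1 at least 650-fold, with 0 counts in spleen. Efemp1 was at least 604-fold, Mmp7 at least 595-fold and Cuzd1 at least 594-fold higher. Quality weights ended the calls of Mmp7 (adjusted p = 0.0988) and Sprr2f (0.0579). Limma-voom ended those of Cuzd1 (0.228) and of Prap1 (0.151), which averaged 2115 ± 2460 CPM. Among the lowest, beside the lower B cell markers, were genes that B cells express, Fcmr (-5.27 ± 0.49), Blk (-4.30 ± 0.54) and H2-DMb2 (-4.11 ± 0.437), with Ly6d (-3.86), Dusp10 (-3.31) and Mef2c (-3.06).

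In all, 5012 genes passed in CD8 cells, 3068 higher and 1944 lower in genital tract. With an estimated correlation the calls of the cytotoxicity, type 1 and type 17 helper, regulatory, inhibitory receptor, cytokine, repair, naive, B cell, epithelial and fibroblast lists held, the weakest being inhibitory receptors (adjusted p = 0.0444). Over genes with at least 1 CPM in spleen, an alternative chosen after the data were seen, 3518 genes passed. Of these 52.6% were higher in genital tract, against 61.2% over all genes, and again a lower share follows from the filter itself.

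**Figure D3:**
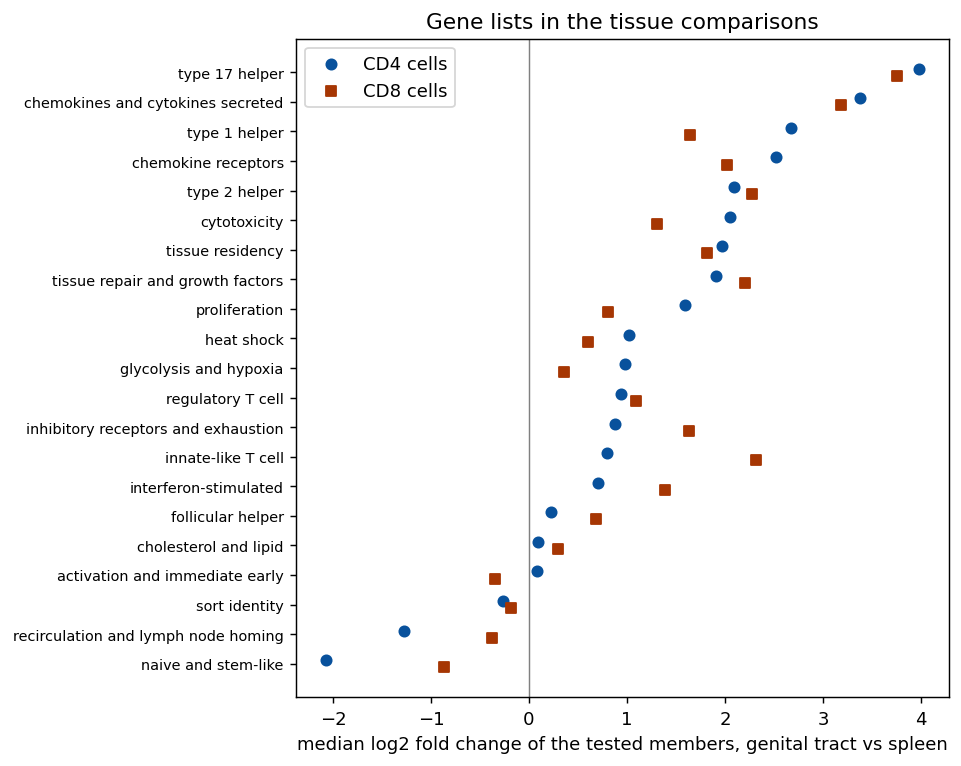
Median log2 fold change of the tested members of each of the 21 lists of T cell functions, genital tract against spleen, with circles for CD4 cells and squares for CD8 cells. Medians run from -2.07 for naive genes to 3.98 for type 17 helper genes in CD4 cells, and from -0.87 to 3.75 for the same lists in CD8 cells.

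Both subsets shared a large part of their tissue difference. Of the genes past the threshold, 1879 were higher in genital tract in both subsets, where independent lists of these sizes would share 562.2. Lower in both were 1090, against 247. Ifng, Gzmb, Cxcr6, Itga1 and Hspa1a were among the shared higher genes, and Ccr7 and Lef1 among the shared lower ones. In opposite directions 30 genes passed. Across the 15019 genes, which are not independent replicates, the fold changes of both comparisons had a Pearson r of 0.811 and a Spearman rho of 0.701. These comparisons have no library in common. Spleens and genital tracts came from the same mice, however, and only genital tracts were digested with enzymes. Fibroblast markers were also at 664 and 1359 CPM in CD4 and CD8 cells of the genital tract, against 1.0 and 0.925 CPM in spleen. The overlap therefore cannot be told apart into T cell differences, markers of other cells and digestion.

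In the genital tract, CD4 and CD8 cells differed in which effector genes they carried. CD4 cells held more cytokine transcripts, with Ifng lower in CD8 cells at -2.34 ± 0.42 (adjusted p = 0.00278) and Il17a at -5.48 ± 0.7 (n = 3 and 3). Foxp3 averaged 120 ± 30.7 CPM in CD4 and 0.853 ± 0.753 CPM in CD8 cells (-7.12 ± 0.525, adjusted p = 3.09e-06). CD8 cells held more of Gzmb (1.77 ± 0.28), of Prf1, the pore-forming perforin gene (4.19 ± 0.244), and of Eomes, at 118 ± 7.82 against 2.79 ± 0.349 CPM (5.40 ± 0.167, adjusted p = 4.97e-10).

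Type 17 helper genes were lower in CD8 cells for 13 of 15 (14 adjusted over the list alone, median -3.76, adjusted p = 2.9e-19). Il21 had -5.87 ± 0.806 and Ccr6 -4.31. Regulatory genes were lower for 12 of 20 (16 adjusted over the list alone, median -1.69, adjusted p = 4.61e-21), with Tnfrsf4, a costimulatory receptor, at -5.70. Type 2 helper genes were lower for 4 of 9 (6 adjusted over the list alone, median -1.84, adjusted p = 3.13e-07), with the receptor gene Ccr4 at -4.17. Secreted cytokines were lower for 13 of 26 and higher for 4 (14 and 4 adjusted over the list alone, adjusted p = 1.13e-06). Csf2 averaged 6.45 ± 0.864 CPM in CD8 and 51.8 ± 15.8 CPM in CD4 cells, and Cd40lg, the helper ligand for B cells and dendritic cells, had -5.06 ± 0.421. Chemokine receptors were lower for 7 of 18 and higher for 3 (9 and 3 adjusted over the list alone, adjusted p = 1.83e-04), with Ccr8 at -4.53. Glycolysis and hypoxia genes were lower for 14 of 23 and higher for 1 (16 and 1 adjusted over the list alone, median -0.56, adjusted p = 4.69e-11), with Hif1a, the oxygen-sensing transcription factor, at -1.86.

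Cytotoxicity genes were higher in CD8 cells for 12 of 19 (12, and 2 lower, adjusted over the list alone, median 1.51, adjusted p = 6.22e-18), with Gzmm at 3.99 and Ccl5 at 2.67. Innate-like genes were higher for 10 of 18 and lower for 1 (12 and 1 adjusted over the list alone, adjusted p = 3.92e-09, and adjusted p = 0.0555 with an estimated correlation), with Klra7 at 6.91 and Cd160 at 4.53. Klra6, a receptor of the same family as Klra7, was at least 422-fold higher. Natural killer cell markers were higher for 5 of 11 (7 adjusted over the list alone, median 1.77, adjusted p = 2.6e-07, and adjusted p = 0.0557 with an estimated correlation). Naive genes were higher for 15 of 21 (15, and 2 lower, adjusted over the list alone, median 1.06, adjusted p = 7.99e-20), including Dapl1 (3.72), Actn1 (2.47) and Cd27 (1.77). Recirculation genes were higher for 7 of 15 and lower for 1 (10 and 1 adjusted over the list alone, adjusted p = 6.4e-11). Residency genes went both ways, with 8 of 23 lower and 3 higher (10 and 3 adjusted over the list alone, adjusted p = 3.48e-04, and adjusted p = 0.176 with an estimated correlation). Cd69 had -0.72 ± 0.12, while Itgae averaged 47.5 ± 13.7 CPM in CD8 and 16.7 ± 4.1 CPM in CD4 cells (adjusted p = 0.00366). Immediate early genes were lower for 9 of 26 and higher for 2 (12 and 2 adjusted over the list alone, adjusted p = 4.68e-04, and adjusted p = 0.32 with an estimated correlation).

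The type 1 helper list did not pass between subsets of the genital tract (6 of 18 lower, 1 higher, 7 and 1 adjusted over the list alone, adjusted p = 0.112, and adjusted p = 0.522 with an estimated correlation). It passed with the replicate number as a block (adjusted p = 0.0442, and adjusted p = 0.369 with an estimated correlation). Without members shared with other lists, its test pointed the other way and passed (adjusted p = 0.0245, and adjusted p = 0.215 with an estimated correlation), with a median of -0.13 over 10 genes. The follicular helper list passed (3 of 10 lower, 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.0402, and adjusted p = 0.204 with an estimated correlation), but not with the block (0.0689). Tbx21 (0.11 ± 0.168, adjusted p = 0.775), Plac8 (-0.06 ± 0.199, adjusted p = 0.908) and Hspa1a (-0.23 ± 0.352, adjusted p = 0.778) did not pass, nor did any of the 16 heat shock genes. Epithelial markers were higher in CD8 cells for 8 of 11 genes (11 adjusted over the list alone, median 2.57, adjusted p = 6.85e-08, and adjusted p = 0.0555 with an estimated correlation). Fibroblast markers were higher for 1 of 16 (median 0.97, adjusted p = 5.7e-04, and adjusted p = 0.357 with an estimated correlation). Macrophage markers were higher for 1 of 16 (adjusted p = 0.0322, and adjusted p = 0.51 with an estimated correlation) and endothelial markers for 1 of 10 (7 adjusted over the list alone, adjusted p = 0.0046, and adjusted p = 0.357 with an estimated correlation). The smooth muscle list passed as a list with none of its 9 genes past the threshold (adjusted p = 0.0432, and adjusted p = 0.522 with an estimated correlation). In all, 730 genes were higher and 855 lower in CD8 cells. The count of 1585 fell to 1024 without CD4 library 1 and to 1027 without CD8 library 3. With an estimated correlation the naive, recirculation, cytotoxicity, type 17, type 2, regulatory, glycolysis, cytokine and chemokine receptor lists held, the weakest being chemokine receptors (adjusted p = 0.0387).

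In spleen, CD8 cells held more cytotoxic and fewer regulatory and type 2, type 17 and follicular helper transcripts than CD4 cells. Nkg7 averaged 1416 ± 69.2 CPM in CD8 (n = 4) and 108 ± 32.7 CPM in CD4 cells (n = 3), a log2 fold change of 3.71 ± 0.186. Gzmb averaged 36.0 ± 10.2 and 11.3 ± 2.0 CPM (1.67 ± 0.283, adjusted p = 0.00212) and Eomes 125 ± 12.4 and 18.7 ± 2.8 CPM (2.74 ± 0.136). Foxp3 was lower in CD8 cells (-5.46 ± 0.412), as were Pdcd1 (-3.17 ± 0.288) and Il10 (-5.07 ± 0.707). Ifng (-0.43 ± 0.382, adjusted p = 0.561) and Tnf (-0.14 ± 0.228, adjusted p = 0.79) did not pass.

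Cytotoxicity genes were higher in CD8 cells of spleen for 11 of 19 (11, and 2 lower, adjusted over the list alone, median 1.54, adjusted p = 1.26e-31), with Gzmm at 5.33. Innate-like genes were higher for 8 of 18 and lower for 1 (9 and 1 adjusted over the list alone, adjusted p = 1.28e-06, and adjusted p = 0.118 with an estimated correlation). Natural killer cell markers were higher for 4 of 11, the same adjusted over the list alone (adjusted p = 6.18e-04, and adjusted p = 0.206 with an estimated correlation). Type 1 helper genes were higher for 8 of 18 and lower for 2, the same adjusted over the list alone (adjusted p = 6.44e-07, and adjusted p = 0.0738 with an estimated correlation), with Tbx21 at 1.36. Regulatory genes were lower for 14 of 20 and higher for 1 (17 and 1 adjusted over the list alone, median -2.02, adjusted p = 6.79e-26), with Lrrc32, an anchor of latent TGF-beta, at -6.34. Type 17 helper genes were lower for 7 of 15 (12, and 1 higher, adjusted over the list alone, median -3.03, or -2.98 with bounds, adjusted p = 1.26e-08). Type 2 helper genes were lower for 5 of 9, the same adjusted over the list alone (adjusted p = 1.17e-07), and follicular helper genes for 4 of 10 with 1 higher (7 and 1 adjusted over the list alone, adjusted p = 1.62e-05). Recirculation genes were higher for 4 of 15 and lower for 1 (5 and 1 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.0994 with an estimated correlation). The naive (3 of 21 higher, 3 lower, 3 and 5 adjusted over the list alone, adjusted p = 0.815) and residency lists (5 of 23 higher, 5 lower, the same adjusted over the list alone, adjusted p = 0.791) did not pass.

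Of single homing and tissue genes in spleen, Plac8 averaged 101 ± 15.8 CPM in CD8 against 9.18 ± 2.18 CPM in CD4 cells (3.46 ± 0.222), Itgae 138 ± 22.7 against 10.7 ± 3.98 CPM (3.69 ± 0.296) and Ccr9 130 ± 14.4 against 5.53 ± 2.46 CPM (4.55 ± 0.302). Ccr7 (0.89 ± 0.327, adjusted p = 0.116, but 0.022 without CD8 library 2 and 0.0327 with DESeq2) did not pass. Cd69 was higher in CD8 cells by 0.51 ± 0.113 (adjusted p = 0.0123, and 0.0643 without CD4 library 1). Runx3, a factor of the CD8 lineage, was higher by 0.49 ± 0.121 (adjusted p = 0.0233, and 0.111 or 0.0971 without CD4 library 1 or 3, and 0.0829 when only these groups were fitted). Among the highest fold changes were those of Slc6a19, an amino acid transporter (7.76 ± 0.427), Bend4 (6.35), Adgrg5 (5.65), Cd163l1 (5.24) and Ly6c2 (4.92 ± 0.221). The lowest included Ly6c1 (-6.21 ± 0.413), the near-identical neighbour of Ly6c2, Cd40lg (-5.71), Myo10 (-5.23), Pdlim4 (-5.16) and St8sia6 (-4.87). B cell markers were higher in CD8 cells for 6 of 16 genes (8 adjusted over the list alone, adjusted p = 1.93e-05, and adjusted p = 0.287 with an estimated correlation) and dendritic cell markers for 5 of 13 (adjusted p = 1.78e-04, and adjusted p = 0.196 with an estimated correlation).

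In all, 614 genes were higher and 732 lower in CD8 than in CD4 cells of spleen. The count of 1346 became 799 without CD4 library 2 and 822 without CD4 library 3, 859 when only the 2 groups were fitted, and 2058 with DESeq2. The 4 CD8 spleen libraries, which also enter the CD8 tissue difference and the interaction, stood apart from each other on the third principal component, libraries 1 and 2 at 4.59 and 20.7 and libraries 3 and 4 at -31.2 and -24.9. Deviations from their group mean correlated across genes at 0.24 between libraries 1 and 2, at 0.16 between 3 and 4, and at -0.71 to -0.49 between the others, and the labels name no batch. Mitochondrial transcripts were at 1.237 and 0.996% in libraries 1 and 2 and at 1.685 and 1.779% in libraries 3 and 4. Genes with at least 1 count numbered 17760 and 17621 against 16615 and 16416. With an estimated correlation the cytotoxicity, regulatory, type 17, type 2 and follicular helper lists held, the weakest being the follicular helper list (adjusted p = 0.0162). The subset differences of both tissues shared 257 higher and 309 lower genes, where independent lists would share 29.84 and 41.67, with 34 opposite. Cd8a, Eomes and Foxp3 were among the shared genes. Across genes the fold changes had a Pearson r of 0.308 and a Spearman rho of 0.265.

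The tissue difference itself differed between CD8 and CD4 cells for 365 genes, 183 with a higher and 182 with a lower fold change in CD8 cells. The values here are differences of log2 fold changes, CD8 minus CD4. Plac8 rose in both subsets and by less in CD8 cells (-3.52 ± 0.293, adjusted p = 2.81e-05), whose splenic level was higher. Cd69 (-1.22 ± 0.165, adjusted p = 0.00142) and Itgae (-2.19 ± 0.387, adjusted p = 0.00965) fell in CD8 cells. For Ifng the difference of -1.91 ± 0.563 did not pass (adjusted p = 0.108), nor did that of Gzmb (0.09 ± 0.388, adjusted p = 0.965) or Ccr7 (1.11 ± 0.47, adjusted p = 0.291).

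Naive genes had a higher fold change in CD8 cells for 11 of 21 and a lower one for 1 (13 and 1 adjusted over the list alone, median 0.94, adjusted p = 7.6e-20), and recirculation genes for 3 of 15 and 1 (6 and 2 adjusted over the list alone, adjusted p = 4.41e-05). Type 1 helper genes had a lower fold change in CD8 cells for 7 of 18 and a higher one for 1 (14 and 1 adjusted over the list alone, median -1.20, adjusted p = 1.04e-08). Tbx21 had -1.25 ± 0.235 (adjusted p = 0.0125), and Eomes 2.65. Chemokine receptors were lower for 7 of 18 (7, and 1 higher, adjusted over the list alone, adjusted p = 8.47e-06), with Ccr9 at -4.53 and Ccr6 at -3.46. Glycolysis genes were lower for 8 of 23 and higher for 1 (14 and 1 adjusted over the list alone, median -0.48, adjusted p = 1.36e-11), with Hk2, which starts glycolysis, at -3.58. The calls of these 5 lists held with an estimated correlation, the weakest being type 1 helper genes (adjusted p = 0.0459). Inhibitory receptor genes were higher for 3 of 15 (4, and 2 lower, adjusted over the list alone, adjusted p = 0.00658, and adjusted p = 0.291 with an estimated correlation). Residency genes were lower for 3 of 23 and higher for 1 (5 and 1 adjusted over the list alone, adjusted p = 0.00282, and adjusted p = 0.368 with an estimated correlation). Cytotoxicity genes were lower for 4 of 19 and higher for 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00723, and adjusted p = 0.368 with an estimated correlation). Lists with at most 1 gene past the threshold in a direction passed too, and none of them did with an estimated correlation. Smooth muscle markers (adjusted p = 0.00282, and adjusted p = 0.526 with an estimated correlation), interferon-stimulated genes (0.0024, and 0.658) and follicular helper genes (0.0486, and 0.3) pointed up. Proliferation genes (adjusted p = 0.00301, and adjusted p = 0.658 with an estimated correlation), immediate early genes (0.00469, and 0.562), B cell markers (0.0486, and 0.658), dendritic cell markers (0.0496, and 0.563) and type 17 helper genes (0.0496, and 0.291) pointed down.

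Among the highest differences of the tissue effect were those of Ly6c1 (6.41 ± 0.55), Bcam (5.64, but adjusted p = 0.0637 with limma-voom), Pdlim4 (5.43), Myo10 (5.23), Arhgap29 (5.21) and Dapk1 (4.56). Epithelial and endothelial markers were at 308 ± 148 and 74.0 ± 75.3 CPM in CD8 genital tract libraries, against 52.2 ± 21.7 and 9.6 ± 6.19 CPM in CD4. Their lists did not pass in the interaction (adjusted p = 0.173 and 0.899). Which cells the transcripts of these genes came from was not tested. Among the lowest beside Ccr9 were Actn2 (-4.15), Serpinb1a (-3.87) and Hk2. Differences for Tnf (-1.41 ± 0.332, adjusted p = 0.0427), Cxcr3 (-0.87 ± 0.18, adjusted p = 0.0218), Cxcr6 (-1.87 ± 0.396, adjusted p = 0.0241) and Zbtb7b, a factor of the helper lineage (1.72 ± 0.39, adjusted p = 0.0352), did not hold in every leave-one-out fit. Adjusted p then reached 0.121 for Tnf, 0.0727 for Cxcr3, 0.0768 for Cxcr6 and 0.099 for Zbtb7b. The count of 365 became 198 without CD4 spleen library 3, 215 without CD4 genital tract library 1, 233 or 236 without CD8 genital tract library 2 or 3, and 792 with DESeq2.

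**Figure D4:**
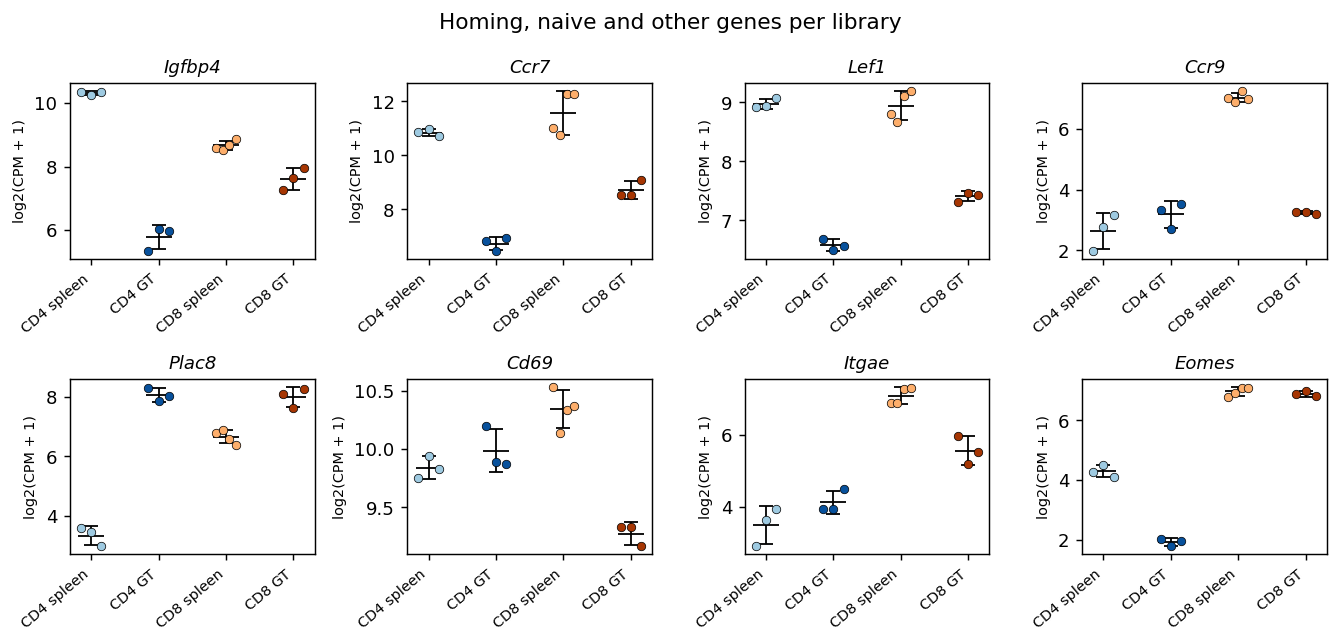
Expression of Igfbp4, Ccr7, Lef1, Ccr9, Plac8, Cd69, Itgae and Eomes as log2(CPM + 1), with 1 point per library and black marks for the mean and bars for the SD on that scale. Igfbp4 is at a mean of 1273 CPM in spleen and 55.4 CPM in the genital tract (GT) in CD4 cells, and at 406 and 198.5 CPM in CD8 cells, while Cd69 is at 1305 CPM in spleen and 620 CPM in GT in CD8 cells.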

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

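Chosen only after the results were seen were the comparison of library totals and the tests of a digest shared by same-numbered libraries and of the digestion.

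In the 4 CD8 spleen libraries, 96 values were checked for a library far from the other 3, measured as its gap to the nearest library over the whole range, against Dixon's 95% critical value for 4 libraries. Chance finds about 1 in 20 such values, and 6 were found. Library 4 stood apart for Tnf (0.954, 17.2 CPM), for Klrk1 (0.832, 18.5 CPM), and for Il17a (1.0), where 1 count was its sum. Library 2 stood apart for Mmp9 (0.905, 1.36 CPM). Library 3 stood apart for Il1rl1 (0.925, 0.872 CPM) and for the summed B cell markers (0.862, 1468 CPM).

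The tissue difference differed between CD8 and CD4 cells for 26 of the 82 genes named for the tissue comparisons. The log2 difference of fold changes, CD8 minus CD4, was positive for Pdlim4 (5.43), Lag3 (5.28), Slc16a5 (3.71), Atp1b1 (3.50), Igfbp4 (3.49), Eomes (2.65), Dapl1 (2.6), Pdcd1 (2.48), Tox (1.90), Cd27 (1.75), Zbtb7b (1.72), Pdk1 (1.41) and Lef1 (0.85). It was negative for Ccr9 (-4.53), Plac8 (-3.52), Furin (-2.72), Ccl4 (-2.43), Itgae (-2.19), Nkg7 (-2.16), Cxcr6 (-1.87), Ccr2 (-1.75), Tpi1 (-1.43), Tnf (-1.41), Tbx21 (-1.25), Cd69 (-1.22) and Cxcr3 (-0.87).

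Genital tract libraries held transcripts of marker genes of fibroblasts, epithelium and neutrophils although cells were sorted on CD3 and CD4 or CD8. The most abundant fibroblast markers, the collagen gene Col3a1 and Serping1, averaged 332 and 178 CPM in CD8 cells of the genital tract, and none of the 16 stood on another list. Library totals differed by at most 0.40 on the log2 scale, and the smallest log2 fold change of these markers in CD4 cells was 4.98 (Fn1). The fold changes were already scaled to library size, so this comparison is no separate test of it. Carry-over of cells or RNA from a digest that same-numbered libraries shared may be a source, since deviations of 59 tissue markers correlated between CD4 and CD8 libraries of a number with a mean r of 0.622 (0.286, 0.782 and 0.798), above the highest r between numbers, 0.473. A T cell source of such transcripts was not tested and stays open, and the r across genes of the first pair was below that highest value.

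The heat shock genes Hspa1a and Hspa1b were higher in genital tract in both subsets. Only genital tracts were digested with enzymes, so the log2 fold change of 10.99 for Hspa1a in CD4 cells cannot be told apart into digestion, tissue and infection. If tissue cells brought these transcripts, Hspa1a could follow the fibroblast markers over the 6 genital tract libraries. Their Pearson r was 0.219 (exact permutation p = 0.685), the Spearman rho 0.371 (exact permutation p = 0.497), and r without the 2 farthest libraries 0.425, and 6 libraries leave this explanation open. A response of T cells to the infected tissue also stays open, as untested.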

How the results depend on the processing

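Fits over genes with at least 1 CPM in spleen were chosen only after the data were seen, and all other alternatives had been planned. Of 433 results for named genes 378 passed the threshold. Of these, 348 lost their call in no leave-one-out fit, 343 in none of the scaling, filter, DESeq2, limma-voom, groups-only and thinning alternatives. With the block 365 kept it. Results that a fit did not test, such as the interaction when only the groups compared were fitted, were counted as not lost. None changed sign with a call. Scaling by other factors moved no share of higher genes by more than 10 points. The counts of genes past the threshold moved by over 1.5 times with DESeq2 (spleen subset 2058, interaction 792), with quality weights (genital tract subset 2515), and when only the groups compared were fitted (spleen subset 859). Requiring a fold change of at least 2 left 2608 genes for the CD4 tissue difference, 2715 for CD8, 911 for the genital tract subset difference and 736 for that of spleen, since fewer genes reach that size. The cause of the other changes was not tested. Leaving out 1 library at a time gave 3384 to 3855 genes for the CD4 tissue difference and 3814 to 5719 for CD8. It gave 1024 to 1202 for the genital tract subset difference, 799 to 1667 for that of spleen and 198 to 546 for the interaction, where fewer libraries were fitted. Over genes with at least 1 CPM in spleen the counts were 3774, 3518, 1582 and 390 for the CD4 and CD8 tissue, genital tract subset and interaction contrasts.

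With the replicate number as a block 4533, 4011, 1563, 1031 and 252 genes passed for the CD4 tissue, CD8 tissue, genital tract subset, spleen subset and interaction contrasts. Only CD8 spleen library 4 carried the number 4, so the block took it out of the contrasts of its group. Without that library and without a block, the CD8 tissue, spleen subset and interaction counts were 4283, 1171 and 328. The lower counts with the block are therefore not those of pairing alone. Same-number deviations correlated at 0.25 to 0.28 between both subsets of the genital tract, and there, of the lists and named genes, the block changed the calls of the type 1 and follicular helper lists and of Ptger2 (adjusted p = 0.0643) and no other. Between CD8 cells of both tissues they correlated at -0.18 to -0.022 and between the subsets of spleen at -0.26 to -0.078. The numbers therefore did not pair the libraries of those comparisons, but a pairing under other numbers was not tested and stays open. CD8 spleen library 2 correlated best with library 3 of CD4 spleen, CD4 genital tract and CD8 genital tract (0.43, 0.32 and 0.28). CD8 spleen library 3 correlated best with library 1 of these groups (0.14, 0.34 and 0.24). CD8 spleen libraries 1 and 4 had no such single number. Between CD4 cells of both tissues the correlations were weaker than in the genital tract, at 0.048 to 0.2. Each CD4 library of spleen still correlated best with its own number there, so a pairing in the CD4 tissue comparison stays open. The main fit ignored it, and 4255 of its 4660 genes also passed with the block. Between CD4 cells of spleen and CD8 cells of the genital tract, which only the interaction brings together, same-number deviations correlated at 0.14 to 0.3. With the block the interaction did not pass for Cxcr6 (adjusted p = 0.0629) and Zbtb7b (0.116). Of 165 list results, 107 were the same and 58 lost their call with an estimated correlation. With the block 159 were the same, 5 gained and 1 lost a call. Without members shared with other lists 151 were the same, 11 lost and 2 gained a call. The test of the type 1 helper list in the genital tract subset difference then changed direction (adjusted p = 0.0245 against 0.112), while its median stayed negative (-0.13), and the cause was not tested. Counts of 0 in spleen limit the fold changes of tissue markers to lower bounds, and the levels of Il17a, Il1rl1 and Mmp9 in CD8 cells of spleen rest on few counts.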

Other observations

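The splits of libraries given here were tests chosen only after the counts of genes were seen.

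Transcripts of ribosomal proteins made up a smaller share of the counts in the genital tract, with 2.77 ± 0.626% in CD4 and 3.85 ± 0.255% in CD8 cells against 4.51 ± 0.446 and 5.83 ± 0.91% in spleen (n = 3, 3, 3 and 4). The 10 most abundant genes took 8.56 ± 1.07 and 7.78 ± 0.863% of the counts in the genital tract against 5.92 ± 0.0781 and 5.89 ± 0.209% in spleen. By its mean CPM Hspa1a was among these genes in both genital tract groups, so this share and the heat shock result are not separate. Mitochondrial transcripts were at 0.884 ± 0.139 and 1.07 ± 0.0864% against 1.01 ± 0.0738 and 1.42 ± 0.371%. The last mean was raised by CD8 spleen libraries 3 and 4, at 1.685 and 1.779%, while libraries 1 and 2 were at 1.237 and 0.996%.

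In spleen, interferon-stimulated genes were lower in CD8 than in CD4 cells as a list, with 3 of 31 past the threshold, the same adjusted over the list alone (adjusted p = 7.6e-04, and adjusted p = 0.735 with an estimated correlation). Ifit2 had a log2 fold change of -1.06 and Isg20 -0.84. Without CD4 spleen library 3 none of the 3 passed (adjusted p = 0.128 for Ifit2, 0.0547 for Isg20 and 0.101 for Ifih1). Ifit2 and Ifih1 also lost their calls in other leave-one-out fits, at up to 0.0869 and 0.0947, and when only these groups were fitted (0.0538 and 0.131), and Ifit2 with no filter (0.0749). Inhibitory receptor genes were lower for 6 of 15 and higher for 2 (7 and 2 adjusted over the list alone, adjusted p = 0.00582, and adjusted p = 0.196 with an estimated correlation), with Cd200r1 at -3.67 and Lag3 at -2.86. In the genital tract, proliferation genes were lower in CD8 cells as a list (2 of 34, 1 adjusted over the list alone, adjusted p = 0.00194, and adjusted p = 0.542 with an estimated correlation). Cholesterol genes did not pass there (8 of 20 lower and 2 higher, 8 and 5 adjusted over the list alone, adjusted p = 0.0667), though Sqle, an enzyme of cholesterol synthesis, had -1.70.

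A hypothesis set beforehand was that T cells of the genital tract use fewer T cell receptor beta variable segments than those of spleen. The effective number of segments, the exponential of the Shannon entropy over 35 segments, averaged 16.47 ± 0.203 in CD4 and 17 ± 0.446 in CD8 cells of the genital tract against 16.82 ± 0.227 and 17.38 ± 0.175 in spleen. The difference of -0.365 had an exact permutation p of 0.0286, 2-sided, over 700 permutations within subset, of which the smallest possible p was 0.00143. With all libraries thinned to 3838 segment counts the difference was -0.372 (exact permutation p = 0.0557), so it no longer passed at that depth although the difference was of like size.

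Libraries were also split in other ways into groups of the real sizes. For the CD8 tissue difference 1 of 35 splits, the real one, gave as many genes as the real 5012, the highest other giving 4035. That other split set spleen libraries 1, 3 and 4 against the genital tract libraries and spleen library 2, so it largely kept the tissues apart. Splits with both tissues in the group of 3 gave 0 genes. For the subset difference in spleen 1 of 35 splits, the real one, gave as many genes as the real 1346. The highest other gave 321, with CD8 library 2 moved to the CD4 libraries. The real split came first in both, which is the smallest share that 35 splits can give. The splits were chosen after the counts were seen, so chance is not excluded. For the CD4 tissue difference (1 of 10 splits, 4660 genes, highest other 0) and the subset difference in the genital tract (1 of 10, 1585 genes, highest other 0) there are too few splits for a share under 0.05. For the interaction the splits exchanged libraries between tissues within a subset, which moves the tissue difference into the interaction, so they do not test whether chance gives the real 365 genes. At least as many genes came from 4 of 60 splits, the real one included, and the highest other count, 4877, from one that gave 3 CD8 spleen libraries the place of genital tract libraries, so the structure behind it is that of the tissues.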
